A study of Rattus norvegicus with 12 samples.

How the data were processed

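Transcripts of the soleus, a mostly slow-fibred postural muscle of the calf, were measured on 12 arrays from 6 female Wistar rats aged 3 months. Per the labels, a CMV-driven plasmid that expresses focal adhesion kinase (FAK, encoded by Ptk2, a kinase at integrin adhesion sites) was electro-transferred into 1 soleus of each rat, and the empty plasmid into the other. The series design describes a paired comparison between opposite legs. Hindlimb suspension began 2 days after transfection and lasted 7 days, and the muscles were taken after 1 day of reloading. Per the labels' protocols, total RNA was extracted with a modified RNeasy kit, reverse transcribed with gene-specific primers and labelled with radioactive dATP.

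The authors deposited 1 intensity per probe and array for 1185 probes. From the values, the scale is linear, with no missing and no negative intensity. Scanning, background subtraction and scaling between arrays are not given in the sources used here. Array medians ran from 3687.5 to 10941.5 and the lowest intensity of an array from 2749.1 to 6962.8. A background therefore seems to be left in the values, which would make fold changes of dim probes too small. The number of arrays, 6 per construct, limits the precision.

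None of the 1185 probe identifiers matched an entry of the reference gene table (0 matches), and the deposited table does not pair them with gene names. Ptk2, the 18 gene lists fixed before the data were examined and the centring on reference genes were therefore not analysed here. At most 2 probes per direction of the main comparison are given by identifier.

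The array medians differed by more than 5%, for which the rule fixed before the data were examined was quantile normalization. Intensities at or below a floor of 6281, the median over arrays of the 10th percentile, were set to the floor, log2 was taken, and the arrays were quantile-normalized with limma 3.58.1 in R 4.3.3. A probe was tested if it lay above the floor on at least 6 of the 12 arrays, which kept 1170 probes and left out 15. FAK minus empty vector was tested with limma's moderated test, with the animal as a block and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The pairing comes from the series design and the animal number in each label. The deviations of the muscles of an animal from their group means correlated across probes at 0.159 to 0.491 in the 6 animals. Muscles of different animals were not compared in this way, so these values do not by themselves check the pairing. Array-level values were compared by an exact two-sided sign-flip test over 6 pairs, whose smallest possible p is 0.0313.

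The rule for named probes took the 10 largest changes per direction among probes past the threshold, with empty places filled by the smallest unadjusted p. Nothing passed, so every place was filled in that way. Of each 10, the probe with the smallest p and the probe with the largest difference are given by identifier, a choice made after their values were seen.

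The animal numbers fall into 2 runs, 418 to 420 and 431 to 433, a possible batch that the labels do not name. The construct comparison was planned within each run, together with the interaction; the test of the difference between runs was added after seeing the data. Other settings chosen before the data were examined changed the block, the scaling, the floor, the filter, the prior variance, the test and the threshold, and left out each animal in turn. Wherever animals were left out, the floor, the filter and the normalization were set anew on the remaining arrays. Settings chosen after seeing the data put the floor after normalization, dropped it, subtracted the 2nd percentile of each array as background with scaling to the 75th percentile, left out animals 418 and 420, or weighted the arrays.

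The fit was tested on simulated data in which 200 of the 1170 probes had known changes, with the leg differences of each probe at random signs as noise. As means over 10 simulations, it recovered 65.7% of changes of 0.5 on the log2 scale, 95.5% of 2-fold changes and 100% of 4-fold changes, with 1, 3.2 and 5.3 unchanged probes called. The median estimate was 0.79 for a log2 rise of 1 and 1.38 for a rise of 2. The random signs remove deviations that probes share within a pair. The changes were added to values already floored and normalized, and no background was simulated. The recovered shares are therefore upper guides.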

Results

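Transcript levels were measured in 12 soleus muscles of 6 rats, 6 muscles transfected with a FAK expression plasmid and 6 with the empty plasmid. Each rat gave 1 muscle of each kind, taken 1 day after the end of 7 days of unloading. The comparison asks which transcripts differ with the FAK plasmid in a reloading muscle, within the same animal. Ptk2 could not be read here, so no value shows that FAK was raised in any muscle. Each muscle had its own array of 1185 probes.

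The empty-vector array of animal 418 was the dimmest, with a median intensity of 3687.5 and its brightest probe at 146260. On this array 1090 probes (92.0%) lay at or below the floor of 6281. In animal 420, 709 probes of the empty-vector array and 714 of the FAK array did so, and in animals 431 to 433 between 0 and 9 per array. The log2 array median was 13.04 ± 0.34 (SD, n = 6) in FAK muscles and 12.95 ± 0.65 (SD, n = 6) in empty-vector muscles. It was higher in the FAK leg of 3 of 6 animals. The difference was 0.09 ± 0.59 (SD, 6 pairs), with no sign of a shift from 0 (exact sign-flip test, two-sided p = 0.875).

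**Figure D1:**
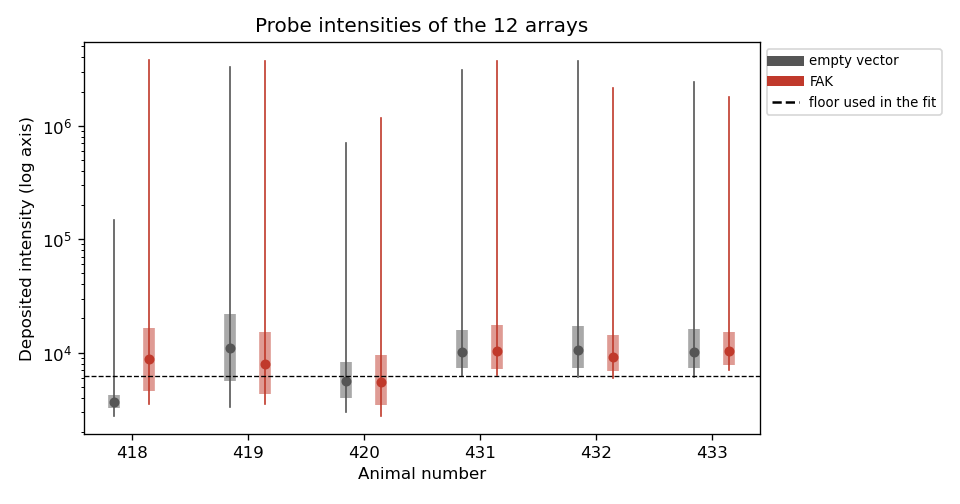
Deposited intensity of the 1185 probes on each array (log axis) by animal number, with the empty-vector array in grey and the FAK array in red. Thin lines span the lowest to the highest probe, thick bars the 10th to the 75th percentile, points the median and the dashed line the floor of 6281, above the median of 3687.5 of the empty-vector array of animal 418.

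No probe passed the threshold between FAK and empty-vector muscles. Of 1170 probes, 0 were higher and 0 lower in limma's paired fit, with a smallest adjusted p of 0.786. At an unadjusted p under 0.05 there were 63 probes, 47 higher and 16 lower in FAK muscles. The nominal 5% of 1170 probes is 58.5, which assumes calibrated p-values. Of 32 splits that exchange legs within animals, the real one included, 4 gave at least 63 probes, with 88 as the highest. The other splits gave 5 to 54. Without the animal as a block there were 36, with 0 past the threshold. In an exact sign-flip test per probe, 33 probes had the smallest possible p of 0.0313, namely the 29 higher and the 4 lower in the FAK leg of all 6 animals. Chance gives 36.6 such probes. Its count of 0 after adjustment carries no information, since 732 probes would have to share that p for any to pass. A paired test without limma's moderated variances passed 0, with 49 at an unadjusted p under 0.05.

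The count of 63 and its split by direction moved with the animal left out, the floor and the scaling. Leaving out an animal also set floor, filter and normalization anew, so its own part cannot be told apart from theirs. With all 6 animals the count was 46 with the floor at the 25th percentile and 120 with no floor. The count was 26 without animal 419 and 100 without animal 433. Without animal 418 it was 67, with 31 probes higher and 36 lower. With background subtraction 47 were higher and 90 lower, and with median centring 18 were higher and 2 lower. Probes with 1 direction in every animal also varied. There were 11 higher and 74 lower without animal 418, and 87 higher and 23 lower without animal 433, where chance gives 66.7 and 70.9 in all. The excess of lower probes was not particular to leaving out animal 418. Without animal 419 there were 15 higher and 66 lower, and without animal 420 44 and 41. Without animal 431 there were 36 and 9, and without animal 432 46 and 14. All 6 animals with the floor at the 25th percentile gave 10 higher and 31 lower (29.2 by chance). With background subtraction there were 21 higher and 49 lower (31.0 by chance), and with quantile normalization and no floor 34 higher and 29 lower (36.6 by chance). Exchanging legs within animals gave up to 128 such probes with background subtraction and up to 119 with no floor.

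The median absolute log2 difference was 0.06 and the median standard error 0.07. For 1124 of the 1170 probes (96.1%) the 95% interval excluded a 2-fold difference in either direction on the normalized scale. Of the 405 probes above the floor on at least 11 arrays, 363 had such an interval. With background subtraction 773 of 991 probes (78.0%) did. The floor, and any background left in the values, can make differences smaller. In simulated data a log2 rise of 1 had a median estimate of 0.79. There the changes were added to values already floored and normalized, so shrinkage by a background was not measured. The estimate itself lay beyond 2-fold for 2 probes.

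**Figure D2:**
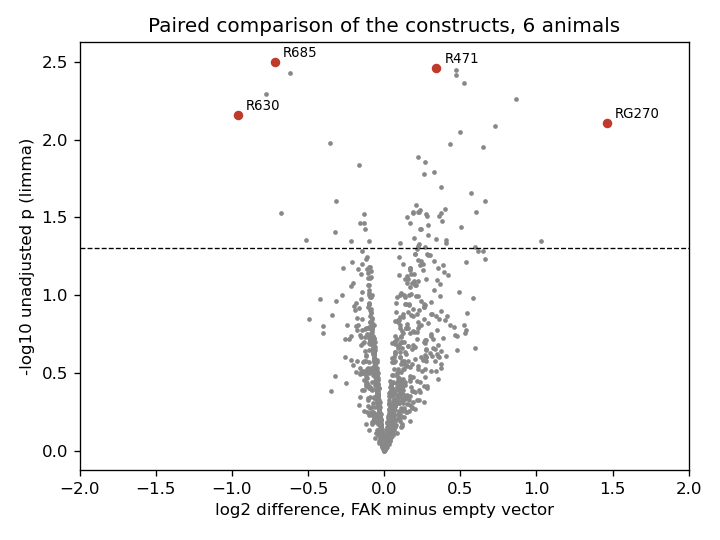
Log2 difference between FAK and empty-vector muscles (x axis) against −log10 of limma's unadjusted p (y axis) for 1170 probes as grey points, with the 4 probes given by identifier in red. Above the dashed line at an unadjusted p of 0.05 lie 63 probes, of which 0 passed after adjustment.

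Probe RG270 had the largest positive difference. Its deposited intensity was 43082.5 ± 42941 (SD, n = 6) in FAK muscles and 9285 ± 3257 (SD, n = 6) in empty-vector muscles. The normalized difference was 1.46 (SE 0.40) on the log2 scale, or 2.75-fold, with a limma adjusted p of 0.786. The FAK leg was higher in 5 of 6 animals. The normalized difference of RG270 was 8.59-fold in animal 431, 3.99-fold in animal 432, 3.06-fold in animal 419 and 1.27-fold in animal 420. In animal 418 the deposited intensity was 38691 in the FAK leg and 3663 in the empty-vector leg, which is below the floor, so its normalized difference, and with it the mean over 6 animals, has no exact size. Without animal 418 the mean log2 difference of RG270 was 1.47. In animal 433 its deposited intensity was 10924 in the FAK leg and 11157 in the empty-vector leg.

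Probe R471 had the smallest p among probes with higher values in FAK muscles. Its normalized log2 level was 13.66 ± 0.14 (SD, n = 6) against 13.32 ± 0.31 (SD, n = 6), a 1.27-fold difference with a limma adjusted p of 0.786, higher in the FAK leg of 6 of 6 animals. The log2 difference of R471 was 0.34, and 0.19 without animal 418 as well as without animal 419, with floor and normalization set anew. In the main setting its leg differences were 0.59 in animal 418, 0.38 in animal 419 and 0.55 in animal 420. The fall to 0.19 therefore cannot be assigned to the animal left out. The empty-vector intensities of R471 in animals 418 and 420, 3415 and 5495, lay below the floor, so its mean difference has no exact size. Its FAK intensity in animal 420, 7019, lay little above the floor. R685 had the smallest p among probes with lower values. Its log2 difference was -0.72 (SE 0.16), with a limma adjusted p of 0.786, lower in the FAK leg of 6 of 6 animals, but it was -0.26 without animal 419 and -0.18 without animal 420. R630 had the largest negative difference, -0.96 (SE 0.26), with a limma adjusted p of 0.786, also lower in 6 of 6 animals. With median centring R685 and R630 were at -0.30 and -0.39, and with the values as deposited at -0.32 and -0.41. The signs per animal are those of quantile-normalized values. In animal 418, whose empty-vector array was dim, deposited intensities were higher in the FAK leg for R685 (23493 against 6939) and R630 (214786 against 95294). In animal 432 the deposited intensity of R471 was lower in the FAK leg (13735 against 15384). The 10 probes with the smallest p per direction differed by 1.27-fold to 2.75-fold where higher and by 1.09-fold to 1.95-fold where lower, and 4 of each 10 had 1 direction in all 6 animals.

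**Figure D3:**
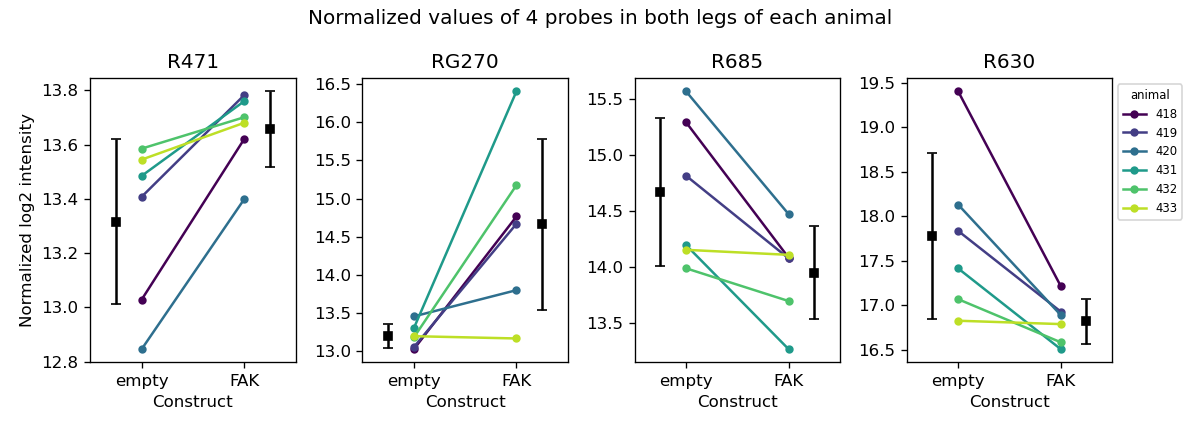
Normalized log2 intensity of 4 probes in the empty-vector and the FAK leg, with a line per animal and black squares with bars for the mean and SD of 6 muscles. In animal 433 the leg differences of RG270, R685 and R630 were -0.03, -0.04 and -0.04.

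Leaving out animal 433 brought 1 probe past the threshold. That probe, R251, was chosen after its values were seen. Over the other 5 animals its log2 difference was -1.01 (SE 0.10), with a limma adjusted p of 0.0328, where the smallest adjusted p of the alternatives ran from 0.0328 to 0.999. Over all 6 animals it was -0.78 (SE 0.19), with a limma adjusted p of 0.786. The normalized leg differences of R251 lay between -1.38 and -0.78 in the 5 animals and at 0.26 in animal 433. In animal 418 its deposited intensity was higher in the FAK leg, 37290 against 10303, and in animal 433 lower, 57391 against 61566, so that the signs of deposited and normalized values were opposite in both animals. Leaving out any other single animal passed 0 probes.

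Of the spread of normalized values, 24.6% lay between the 2 runs of animal numbers, 31.4% between animals within runs and 10.7% between constructs, where their degrees of freedom alone give 9.09%, 36.4% and 9.09%. Between runs, 17 probes passed the threshold in limma's fit of animal means, 7 higher and 10 lower in animals 431 to 433. That count was 0 with median centring and 440 with the values as deposited. Within animals 418 to 420 the construct comparison passed 0 of 1114 probes (limma, smallest adjusted p = 0.0856), with 107 at an unadjusted p under 0.05. Within animals 431 to 433 it passed 0 of 1087 (limma, smallest adjusted p = 0.347), with 76. The interaction of run and construct passed 0 of 1170 (limma, smallest adjusted p = 0.155), with 34 at an unadjusted p under 0.05.

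The leg differences of the 1170 probes were compared between animals in 15 pairs. Pearson's r was 0.496 for animals 419 and 431, 0.481 for 431 and 432, and 0.422 for 419 and 432, and between -0.258 and 0.227 for the other 12 pairs. With background subtraction the highest r was 0.543, for animals 418 and 420, and the 3 pairs above had 0.448, 0.379 and 0.370. Spearman's rho of these 3 pairs in the main setting was lower than r, at 0.349, 0.310 and 0.354. These are correlations across probes, which are not independent replicates.

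**Figure D4:**
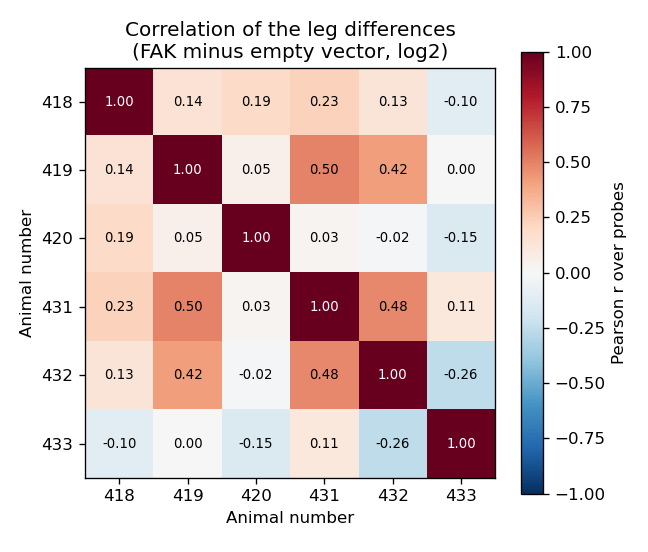
Pearson's r over 1170 probes between the leg differences (FAK minus empty vector, log2) of each pair of animals, with animal numbers on both axes and r as colour and as text. The highest values are 0.496, 0.481 and 0.422, among animals 419, 431 and 432.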

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

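The interaction of run and construct and both tests on the dim array were chosen before their results were seen. The test of the difference between runs, the splits of the animals and the tests on the correlation of leg differences were chosen after. Of 22 groups of values examined, 2 held a value far from the others, where chance gives 1.1.

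The leg differences of animal 418 had an SD over probes of 0.646, far from the 0.181 to 0.290 of the other animals, in the pair with the dim empty-vector array. The 1090 probes at the floor of that array share the same normalized value. For them the leg difference is the FAK level minus a constant, which by itself can widen the SD. With background subtraction the SD was 1.11 in animal 418 and 0.463 to 0.687 in the others. The brightest probes gave no sign of RNA of another tissue on the dim array. Of the 20 brightest probes of the other arrays, 17 were among its own 20 brightest, against 16 to 18 on the others. This cannot decide, since no array of another tissue shows how many would be shared, and a mixture with muscle RNA could keep them. A weak signal over a background stays open: the Spearman correlation with the other leg was low over dim probes (0.631 against 0.831 to 0.955), but also over the 119 brightest probes (0.773 against 0.881 to 0.921). No biological explanation was tested.

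The FAK array of animal 433 had a median Spearman correlation across probes of 0.905 with the other arrays, far from the 0.938 to 0.949 of the other FAK arrays, while the empty-vector arrays of animals 418 and 420 had lower values, 0.728 and 0.849.

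The leg differences correlated among animals 419, 431 and 432, though with background subtraction animals 418 and 420 had the highest r, 0.543, against 0.448, 0.379 and 0.370. For the former, a trend with intensity left after normalization is argued against. Each r kept at least 0.997 of its value after a loess trend was removed. Quantile normalization came first and can itself remove such a trend, so this test does not reach the values as deposited or background-subtracted. Over the 585 brighter probes each kept at least 1.04 of its value, so the dimmer probes did not carry r. Pearson's r weighs large differences most, so this test had little room to come out otherwise. Values near the background therefore stay open. Exchanged labels in animal 433 stay open: its r with the 3 animals was 0.00, 0.106 and -0.258, but that of animal 420 was no larger than 0.050, so an exchange need not give clearly negative values, and exchanging the legs of animal 433 raised the count at an unadjusted p under 0.05 from 63 to 88. A response to FAK that differed between animals, unequal uptake of the plasmid and array lots that differed between legs stay open and were not tested.

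The runs of animal numbers differed in 17 probes. A constant background on each array stays open: 66 probes passed after background subtraction, but that setting also changed floor and scaling, and the count also moved to 56 with no floor and to 0 with the floor at the 25th percentile, where the filter kept 934 probes. A batch of arrays or labelling (17 probes) and a difference between the animals cannot be told apart, since each animal belongs to 1 run and the labels name no batch. The 10 splits of the animals into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave 17 probes, and the highest other gave 1. For the interaction with the construct, 3 of the 10 splits gave as many as the real 34 probes at an unadjusted p under 0.05, and the highest other gave 47.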

How the results depend on the processing

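Background subtraction, the floor after or absent from quantile normalization, array weights, leaving out both animals 418 and 420, and all alternatives for the runs were chosen after seeing the data. The count of 0 probes between constructs held under 24 of 25 alternatives, among them the exact sign-flip test, which could pass a probe only with 732 at its smallest p and so says nothing about stability, and leaving out each animal gave 0 to 1 (1 without animal 433). The smallest adjusted p ran from 0.0328 to 0.999. The 63 probes at an unadjusted p under 0.05 became 36 without the replicate block, which changed no call. They became 5 with the values as deposited, 20 with median centring, 33 with the exact sign-flip test, and 10 with probes above the floor on all 12 arrays, which is 10.6% of the 94 tested against 5.38% of 1170. There the smallest adjusted p was 0.0654, with 4 probes under 0.10. They became 120 with 1 percent of the median added in place of a floor, 120 with quantile normalization and no floor, 119 with the floor after it, 137 with background subtraction and 147 with array weights. Fewer animals gave 107 (418 to 420 alone), 127 (418 and 420 left out), 122 (the same with background subtraction) and, leaving out each animal, 26 (without 419) to 100 (without 433). The causes of these changes were not tested. The signs of the 4 named probes held wherever they were tested, but their sizes moved with the scaling. The log2 differences of R630 and R685, -0.96 and -0.72 in the main setting, were -0.39 and -0.30 with median centring. With the values as deposited they were -0.41 and -0.32. Background subtraction moved RG270 from 1.46 to 2.23 and R471 from 0.34 to 0.62. Leaving out each animal gave log2 differences of 1.15 to 1.81 for RG270, 0.19 to 0.37 for R471 (0.19 without 418 and without 419), -0.87 to -0.18 for R685 (-0.26 without 419, -0.18 without 420) and -1.13 to -0.73 for R630. These fits also set floor, filter and normalization anew, so the shifts cannot be assigned to the animal left out. The difference between runs gave 0 to 440 probes. Missing values at the floor were not run because none was missing. Reference genes, gene lists and Ptk2 were not run because no probe identifier could be paired with a gene name here. Signal over background limits animal 418 most, with 1090 probes at the floor on 1 array. The other arrays of animals 418 to 420 had 202 to 714 probes at the floor.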

Other observations

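The test of the mean correlation, and the settings with background subtraction and with no floor, were chosen after results were seen. Exchanging legs within animals gives 32 splits, the real one included. For probes past the threshold the real count was 0, which all 32 splits must reach, so this says nothing about chance; the highest other gave 0. For the other 4 results chance is not excluded. At an unadjusted p under 0.05, 4 splits gave as many as the real 63, with 88 as the highest other. With background subtraction 2 splits gave as many as the real 137, with 210 as the highest other, and with quantile normalization and no floor 2 gave as many as the real 120, with 169. For the mean correlation of leg differences over the 15 pairs of animals, 3 splits gave at least the real 0.116, with 0.170 as the highest other. The highest other split in these 4 results was the one that exchanged only the legs of animal 433.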
